A study of Mus musculus with 2 samples.

How the data were processed

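Ribosomal-RNA-depleted total RNA from FACS-sorted naive CD4 and naive CD8 T cells of Foxp3-GFP mice was sequenced as 1 library per cell type, with a SOLiD low-input whole-transcriptome preparation per the labels' protocols. TopHat, HTSeq and the mouse build mm9 are named in the submitters' processing notes, without versions. The gene annotation, the strand setting and the handling of reads that map to several places are not given in the sources used here. The deposited values are RPKM, read counts normalised to gene length and library total, as the authors' files give them, with a gene symbol and 1 value on each row. Each library had 26882 rows for 23167 symbols. The 2597 symbols on more than 1 row carried identical values on all their rows and were counted once. Groups were taken from the cell type in the labels. Gene names are those of the files. No coordinates are given, because the annotation at hand is of another build (GRCm38) and coordinates were not converted.

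Whole reads were recovered from the RPKM. The ratio of the values of low genes gave the ratio of the library totals, and the totals were those at which each gene's length came out whole, with GENCODE M21 transcript lengths setting the scale. The totals behind the deposited RPKM were 24741945 reads for CD4 and 23853921 for CD8. At these totals all 12735 genes above 0 in both libraries had whole reads within the printed precision of 9 decimals or 10 significant digits, and with the CD8 total moved by 1000 reads 14 of 1000 genes did. A common multiple of a gene's reads and length cannot be read from the values, so the length nearest to an annotated one was taken. Lengths were at their smallest possible value for 79.3% of genes. Recovered reads summed to 1.06 times the totals in both libraries, and the cause of this excess was not tested. Some genes' reads may be multiples that are too high, which would make their intervals too narrow. The ratio between libraries does not depend on the length taken.

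With 1 library per group no test across samples was possible and no p-value is given. The fixed statistic was log2((CD4 RPKM + 1)/(CD8 RPKM + 1)), with a pseudocount of 1 RPKM, which understates the difference of low genes. Genes with an RPKM of 1 or more in at least 1 library were compared, and an absolute log2 difference of 1 or more was counted as at least 2-fold. Folds quoted for single genes are ratios of the deposited RPKM without the pseudocount, with an exact (Clopper-Pearson) 95% interval from the split of the gene's reads, scaled by the library totals. These intervals cover counting error only and compare the libraries, not the cell types. The median log2 difference of each of 26 gene lists and 12 cell type marker lists, fixed before the data were examined, was placed among the medians of 10000 random lists of the same size matched on mean log2(RPKM + 1) in 20 quantile bins. Lists with fewer than 3 measured members got no percentile, and a median outside the 2.5 to 97.5 percentiles is described as standing apart. This is a description of these libraries. The pattern for T cell receptor and immunoglobulin segments matched only Tradd and Ighmbp2, which are not receptor segments, so that list measured nothing of its name.

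Genes were named by a rule fixed before the data were examined. It took the 12 largest log2 differences in each direction among genes with an RPKM of 5 or more in the higher library, leaving out small noncoding RNAs, receptor segments and symbols on more than 1 row. It added all members of the CD4 and CD8 lineage lists with Tet1, Tet2, Tet3, Dnmt1, Dnmt3a and Dnmt3b, and up to 4 members of each other list, the 2 highest by mean RPKM and the 2 with the largest absolute difference. Genes named outside it are said to be so where they appear. Some genes that the rule takes are not reported here.

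Alternatives set before the data were examined were pseudocounts of 0.1 and 5 RPKM, no filter, a filter at 5 RPKM, centring on the median gene, rescaling each library to a sum of 1000000, rescaling to the housekeeping list, leaving out small noncoding RNAs and receptor segments, and narrower gene sets for the all-gene median and correlation. Leaving Rn45s out of the totals and counting only genes with a counting interval on 1 side of 1 were added after seeing the data. The calculations were tested on simulated libraries of 14352 genes with the real lengths and totals. Both totals were found exactly, the simulated ratio of reads was found for 100% of genes and the simulated reads for 97.8%, with lengths drawn from those recovered here. Intervals held the simulated fold for 95.2% of 10051 compared genes. Of 200 changed genes, all 66 at 3-fold and all 63 at 8-fold passed the size rule and none of 71 at 1.5-fold did. Of 9851 unchanged compared genes, 17 passed it. The simulation held counting error only, so this count leaves out differences between animals, sorts or library preparations. Of 400 random lists of 20 genes, 5.5% lay outside the 2.5 to 97.5 percentiles. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.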

Results

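The transcriptomes of naive CD4 and naive CD8 T cells, the resting helper and cytotoxic precursors of the peripheral T cell pool, were compared in a series on 5-hydroxymethylcytosine (5hmC), the oxidised form of 5-methylcytosine made by the Tet enzymes. Cells were sorted from mouse spleen and lymph nodes as CD62L-high, CD44-low, CD25-negative and Foxp3-GFP-negative. There was 1 library per cell type, so no difference below has a replicate check. The library totals behind the deposited RPKM were 24741945 reads for CD4 and 23853921 reads for CD8. Among the 10228 compared genes the median gene had 966 reads in CD4 and 909 in CD8, and 1 RPKM stood for about 70.2 reads in a gene of median length in the CD4 library. Xist was at 15.1 RPKM in CD4 and 15 RPKM in CD8. Outside the naming rule, Ddx3y had 0 reads in CD4 and 1 in CD8, and Eif2s3y, Kdm5d and Uty were listed at 0 in both libraries. The ribosomal protein gene Rpl26 and the complex I gene Ndufs5, which all these cells use and which were picked outside the rule after their values were seen, were listed at 0 in both libraries too, so a listed 0 is not read here as low expression.

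Of the 10228 compared genes, 9583 were at 1 RPKM or more in both libraries, and the coreceptor genes were among the largest differences. Cd4, the coreceptor for MHC class II, was at 305 RPKM in CD4 and 8.89 in CD8, a 34.3-fold difference (95% counting interval 31.7 to 37.1). Cd8a, which encodes a chain of the coreceptor for MHC class I, was at 518 RPKM in CD8 and 2.5 in CD4, a 207-fold difference (180 to 240). By the size rule 247 genes were at least 2-fold higher in CD4 and 314 were at least 2-fold higher in CD8, while 9667 genes (94.5%) differed by less. At 4-fold the counts were 39 and 79. The median log2 difference (CD4 minus CD8) of the 9583 genes at 1 RPKM or more in both libraries was 0.08, and across the 10228 compared genes the libraries had a Pearson r of 0.95 and a Spearman rho of 0.953, where genes are not independent replicates. Of the genes past the size rule, 54 of those higher in CD4 and 50 of those higher in CD8 were small noncoding RNAs. The balance depended on scaling. With each library rescaled to a sum of 1000000, that median moved by 0.19 and 471 genes were higher in CD4 (62.4% of those past the size rule, against 44.0%) and 284 in CD8. That rescaling put Mbd3, Ctla4, Rplp1, Hist1h4c, Hist1h1c and Rnu73b under the size rule, and a pseudocount of 5 RPKM put 17 of the named genes under it, Foxp3, Tbx21, Ikzf2, Ctla4, Mbd3 and Runx1 among them.

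**Figure D1:**
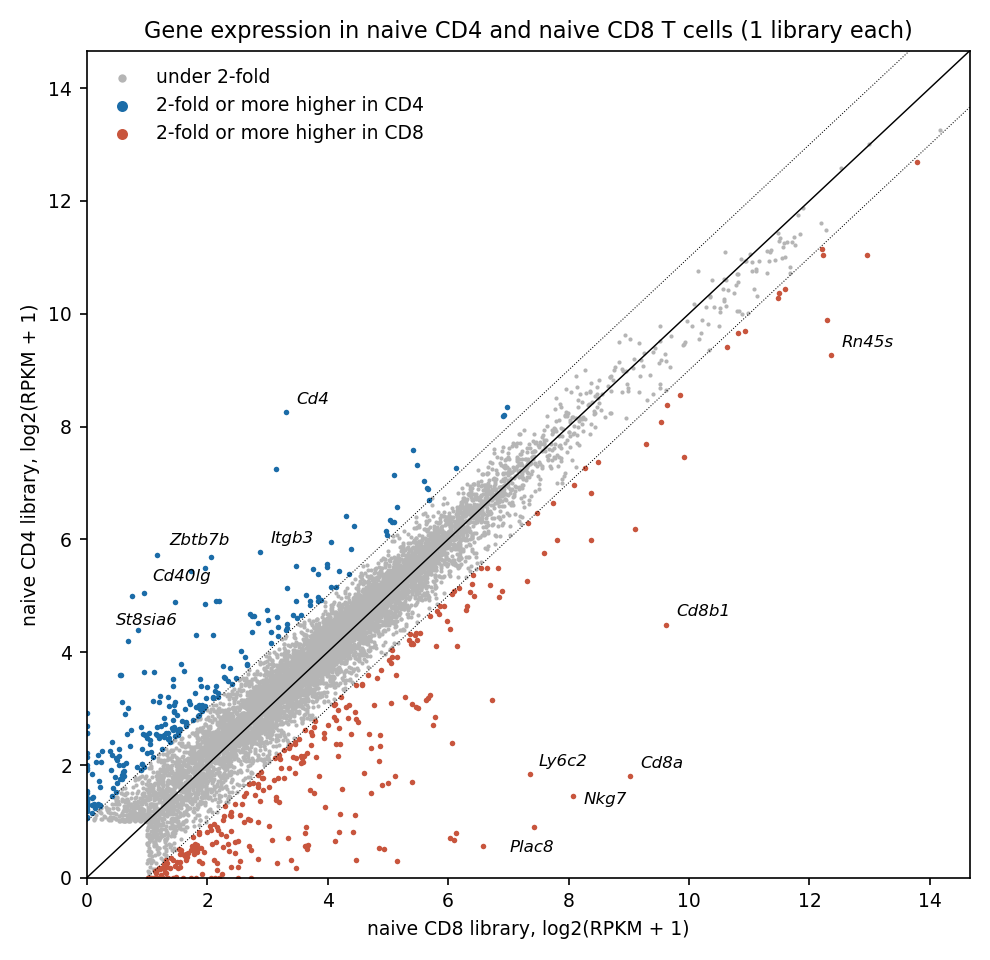
Expression of 10228 genes in the naive CD8 library (horizontal axis) and the naive CD4 library (vertical axis), each as log2(RPKM + 1), with 1 library per cell type. Blue points are the 247 genes at least 2-fold higher in CD4, red points the 314 at least 2-fold higher in CD8, dotted lines mark 2-fold and the solid line equality, and Cd4 and Cd8a lie far from the line on opposite sides.

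The largest differences toward CD4 were in Cd4 and in Zbtb7b, the transcription factor ThPOK that directs CD4 commitment, at 51.8 against 1.25 RPKM (41.4-fold, 34.3 to 50.5). The sialyltransferase gene St8sia6 was at 30.9 against 0.692 RPKM (44.6-fold, 36.7 to 54.7), and Cd40lg, the ligand by which helper cells engage CD40, was at 31.9 against 0.943 RPKM (33.8-fold, 23.3 to 51.2). The remaining genes of the 12 largest were Pdlim4, Lgmn, Adh1, Gm15708, Myo10, the integrin gene Itgb3, 2210010C17Rik and the kinase gene Mapk11. Their folds ranged from 8.53 for Itgb3, at 54.0 against 6.33 RPKM, to 28.7 for Adh1, at 17.3 against 0.601 RPKM. Ly6c1, at 42.4 against 2.33 RPKM (18.2-fold, 14.7 to 22.7), had a difference of that size but stands on more than 1 row and was left out by the rule for the largest differences.

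Toward CD8 the largest differences after Cd8a were in Nkg7, a cytotoxic granule gene, at 267 against 1.75 RPKM (153-fold, 110 to 220), and Plac8, at 172 against 0.877 RPKM (195-fold, 118 to 350). Ly6c2, which encodes a Ly6C surface protein, was at 164 against 2.59 RPKM (63.3-fold, 48.0 to 85.2). Ly6c1 and Ly6c2 are close paralogs that can share reads, so both values are uncertain. Cd8b1, the other coreceptor chain, was at 788 against 21.4 RPKM (36.7-fold, 34.2 to 39.6). The chemokine receptor gene Cxcr6 was at 64.1 against 0.641 RPKM, a 100-fold difference (69.9 to 148). Others of the 12 were Haao, Myo1f, Slc6a19, the chemokine gene Xcl1 and Lcn4, with folds from 18.2 for Lcn4 to 148 for Haao. Xcl1 had 3 reads in CD4 and 251 in CD8, which left its 86.8-fold difference with an interval of 29.4 to 424. Itgae, the integrin CD103, was at 67.6 against 0.596 RPKM (113-fold, 89.2 to 146) and was also left out of the 12 because it stands on more than 1 row.

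All 10 measured CD4 lineage genes were above 0 on the log2 scale and 6 were at least 2-fold higher in CD4, with a list median of 1.34 at a percentile of 100 among matched random lists. The 3 CD4 T cell markers, Cd4, Zbtb7b and Cd40lg, had a median of 4.55 at a percentile of 100. The 2 CD8 T cell markers, Cd8a and Cd8b1, had a median of -6.17. The cells were sorted as CD4 and CD8 T cells, so the direction of the coreceptor genes was set by the sort and is no separate finding. Besides Cd4, Zbtb7b and Cd40lg, the lineage genes at least 2-fold higher in CD4 were Trat1, Cd28 and Cd5. Trat1, a T cell receptor adaptor, was at 141 against 33.5 RPKM (4.2-fold, 4.06 to 4.35). The costimulatory receptor gene Cd28 was at 94.4 against 34.6 RPKM (2.73-fold, 2.63 to 2.84). Cd5, a negative regulator of receptor signalling, was at 289 against 120 RPKM (2.42-fold, 2.34 to 2.49). Gata3, a factor needed for CD4 development and Th2 fate, was near 1 at 2.77 against 2.25 RPKM (1.23-fold, 1.01 to 1.51). Icos (1.04-fold, 0.964 to 1.12) was not distinguishable at this depth. Tnfrsf4 was at 1.75-fold (1.46 to 2.10) and Tnfsf8 at 1.21-fold (1.12 to 1.30).

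Of 10 measured CD8 lineage genes, 9 were at least 2-fold higher in CD8, with a list median of -2.99 at a percentile of 0. Besides Cd8a, Cd8b1, Nkg7 and Itgae they were Klrd1, the NK receptor subunit CD94, at 106 against 7.85 RPKM (13.4-fold, 11.5 to 15.8), Eomes, a T-box factor of cytotoxic cells, at 12.6 against 1.83 RPKM (6.91-fold, 5.87 to 8.17), Ctsw at 332 against 62.4 RPKM (5.32-fold, 5.07 to 5.59), Crtam (4.27-fold, 3.99 to 4.57) and Cd7 (4.27-fold, 3.83 to 4.76). Runx3, the factor that represses Cd4 in the CD8 lineage, was at 6.8 against 4.87 RPKM (1.40-fold higher in CD8, 1.24 to 1.58), under the size rule. Klrk1 was below 1 RPKM in both libraries, with 27 and 25 reads.

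**Figure D2:**
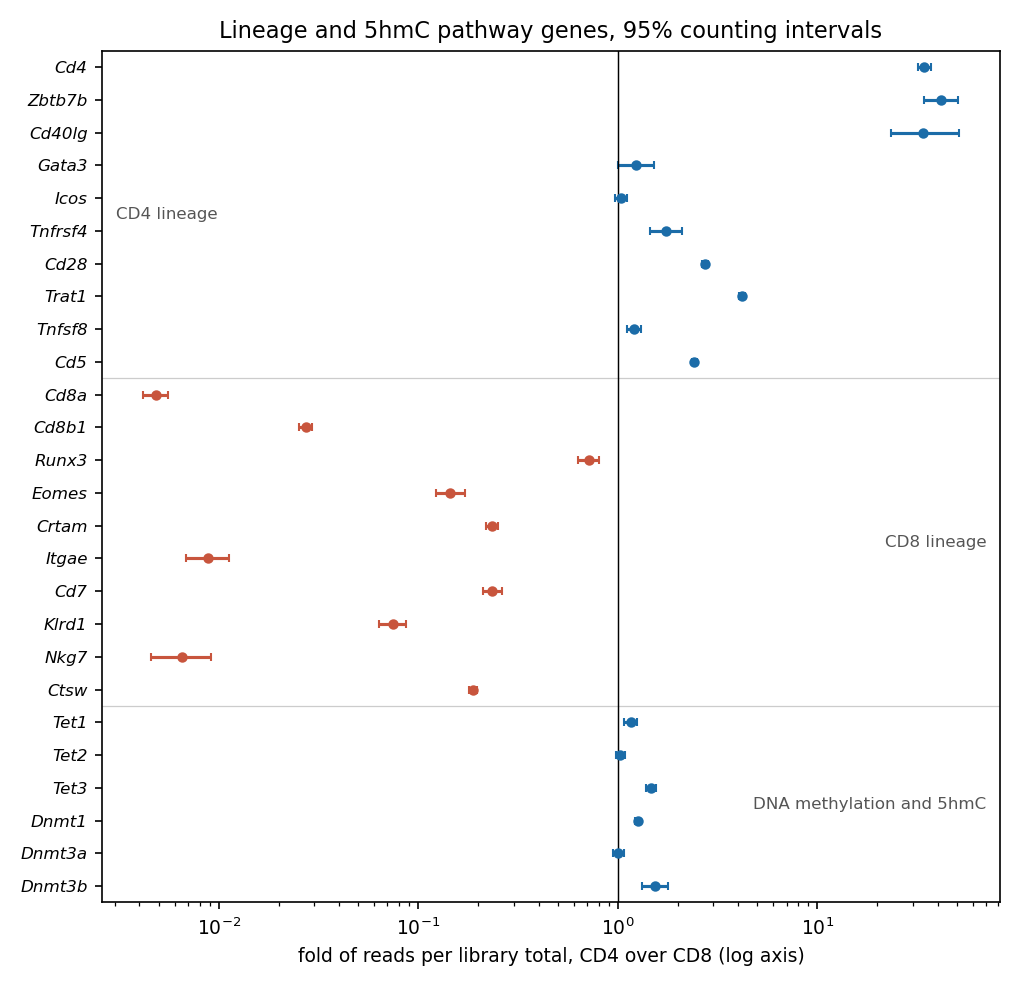
Fold of reads per library total, CD4 over CD8, on a log axis for 10 CD4 lineage genes, 10 CD8 lineage genes and 6 genes of DNA methylation and 5hmC, from 1 library per cell type. Bars are 95% counting intervals, and the Tet and Dnmt genes lie within 2-fold of equality, from 1.01 for Dnmt3a to 1.54 for Dnmt3b, while Cd8a lies 207-fold toward CD8.

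The 24 measured genes of DNA methylation and 5hmC had a median log2 difference of 0.09 at a percentile of 50.9, with 0 genes at least 2-fold higher in CD4 and 2 in CD8. The 3 dioxygenase genes that make 5hmC were expressed in both libraries. Tet2 was the highest, at 13.1 RPKM in CD4 and 12.8 in CD8 (1.03-fold, 0.978 to 1.09), a difference not detectable at this depth. Tet3 was at 9.43 against 6.43 RPKM (1.47-fold higher in CD4, 1.38 to 1.56) and Tet1 at 4.33 against 3.73 RPKM (1.16-fold, 1.08 to 1.25). Of the DNA methyltransferase genes, Dnmt1, the maintenance enzyme, was at 67.6 against 53.9 RPKM (1.25-fold, 1.22 to 1.29), Dnmt3a at 14.5 against 14.4 RPKM (1.01-fold, 0.940 to 1.08) and Dnmt3b at 4.35 against 2.83 RPKM (1.54-fold, 1.33 to 1.79). The exceptions were Cxxc5, a CXXC zinc finger gene, at 17.1 RPKM in CD8 against 0.748 in CD4 (22.9-fold, 16.8 to 32.0), and Mbd3, a member of the methyl-CpG binding domain family, at 43.1 against 19.1 RPKM (2.25-fold, 2.06 to 2.46). Mbd2 and Idh2 were the highest of the list by mean RPKM, at 1.39-fold higher in CD8 and 1.23-fold higher in CD4. The 27 Polycomb and histone modifier genes had a median of 0.06 at a percentile of 32.5 and 0 members past the size rule. Chd4, at 165 and 160 RPKM, and Ehmt2 were the highest, and Rnf2 (1.53-fold higher in CD4) and Hdac1 (1.51-fold higher in CD8) differed most. Centring on the median gene put the Polycomb list at -0.03.

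Cytotoxic and activation genes stood apart toward CD8 in cells sorted as CD44-low. Of 14 measured cytotoxic effector genes, 9 were at least 2-fold higher in CD8 and 1 in CD4, with a median of -1.54 at a percentile of 0. Nkg7 and Xcl1 differed most and Nkg7 and Ctsw were highest. Some genes past the rule were low in CD8 too, with Gzma at 4.51, Ccl4 at 2.87, Tbx21 at 2.63 and Gzmk at 1.12 RPKM. Of these, Gzma, Ccl4 and Gzmk are outside the naming rule and were picked after their values were seen. Fasl, outside the naming rule and picked after its value was seen, was the 1 gene at least 2-fold higher in CD4, at 11.6 against 1.17 RPKM. The 16 activation and memory genes went both ways, with 9 below 0 on the log2 scale and 7 above it. Of them 7 were at least 2-fold higher in CD8, and the median was -0.83 at a percentile of 0. Ly6c2 and the chemokine gene Ccl5 differed most, Ccl5 at 20.4 against 0.765 RPKM (26.7-fold, 14.3 to 56.3). Cd69 was at 81.3 against 42.6 RPKM (1.91-fold, 1.80 to 2.02). The 1 gene of this list past the size rule toward CD4, outside the naming rule and singled out after its value was seen, was Cd44 at 6.33 against 2.6 RPKM. Prdm1, also on this list, was higher in CD4 at 1.24 against 0.171 RPKM, with 158 and 21 reads. It was 7.25-fold higher without the pseudocount and fell under the size rule with it. NK cell markers moved with these groups. Of 6 measured, 5 were at least 2-fold higher in CD8, with a median of -1.82 at a percentile of 0, and Klrd1 and Eomes, both also CD8 lineage genes, differed most. These groups are not separate, since Nkg7 and Ctsw are on the CD8 lineage and cytotoxic lists, Tbx21 and Ccl5 on the cytotoxic and activation lists, and Eomes on the CD8 lineage, activation and NK lists. Prf1 and Gzma, the latter outside the naming rule, are on the cytotoxic and NK lists. Prf1, the perforin gene, was at 54.6 RPKM in CD8 and 34.6 in CD4 (1.58-fold, 1.49 to 1.68). Klrb1c, the 1 measured NKT and gamma delta marker and also on the NK list, had 85 reads in CD8 and 2 in CD4 (44.1-fold, 11.8 to 370).

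Genes of the resting T cell state and of receptor signalling stood slightly toward CD4. The lists are not separate, since Tcf7, Lef1 and Satb1 are on both the naive and the transcription factor lists. Cd28 and Cd5 are on the receptor and CD4 lineage lists, and Zbtb7b and Gata3 on the transcription factor and CD4 lineage lists. The lists in this paragraph were matched on mean expression and not on gene length. Longer genes stood toward CD4 in these libraries (median 0.16 in the longest of 10 equal groups by length), so a part played by length was not tested. The 18 naive and quiescence genes had a median of 0.30 at a percentile of 99.9, with 0 members past the size rule. Of them 16 were above 0 on the log2 scale and 2 below it. Dgka, which limits diacylglycerol signalling, was at 726 against 457 RPKM (1.59-fold, 1.57 to 1.61), Slfn2 at 363 against 221 RPKM (1.64-fold, 1.60 to 1.68) and Ccr7, the lymph node homing receptor, at 453 against 426 RPKM (1.06-fold, 1.04 to 1.08). The 28 receptor complex and signalling genes had a median of 0.18 at a percentile of 99.0, with 2 at least 2-fold higher in CD4, Cd28 and Cd5. Cd3g (673 against 694 RPKM) and Ptprc (580 against 592 RPKM) were the highest and near equal. The 27 T cell transcription factors had a median of 0.22 at a percentile of 98.4. Besides Zbtb7b, Runx1 was at least 2-fold higher in CD4, at 7.06 against 2.77 RPKM (2.55-fold, 2.30 to 2.84), and Id2, outside the naming rule and named after its value was seen, was the 1 factor past the size rule toward CD8. Ets1 was at 792 against 490 RPKM (1.62-fold, 1.60 to 1.63) and Tcf7 at 354 against 284 RPKM (1.25-fold, 1.22 to 1.27).

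Of the 7 measured regulatory T cell genes, 3 were at least 2-fold higher in CD4 and 2 in CD8, with a median of 0.86 at a percentile of 99.99. Folr4, which encodes a folate receptor family protein of the T cell surface, was at 56.0 against 20 RPKM (2.8-fold, 2.59 to 3.02) and Tnfrsf18 at 50.6 against 49.2 RPKM. Foxp3, the regulatory T cell factor whose GFP reporter was sorted against, had 136 reads in CD4 (1.40 RPKM) and 15 in CD8 (0.161 RPKM), an 8.74-fold difference (5.12 to 16.0). Ikzf2 (5.03-fold, 4.39 to 5.79) and Ctla4 (2.26-fold, 1.89 to 2.71) were higher in CD8. The list fell within the range of random lists with no filter on low values (median 0.20) and with a filter at 5 RPKM (median 0.039). The 4 measured regulatory T cell markers, all also in this list, had a median of -0.48 at a percentile of 3.43. Of 5 measured helper effector genes 1 passed the size rule, Tbx21, the T-bet gene, at 2.63 RPKM in CD8 against 0.222 in CD4 (11.9-fold, 6.86 to 22.2). Their median was -0.48 at a percentile of 4.78, and the highest members by mean RPKM were Bcl6 (1.19-fold higher in CD4) and Cxcr5 (1.69-fold higher in CD8).

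Receptors for cytokines and for migration went both ways. Of 21 cytokine receptor genes 2 were at least 2-fold higher in each library, with a median of 0.15 at a percentile of 89.5. Il2rb, the beta chain shared by the IL-2 and IL-15 receptors, was at 44.1 RPKM in CD8 against 7.01 in CD4 (6.29-fold, 5.80 to 6.82) and Il18rap at 4.11 against 0.524 RPKM (7.84-fold, 6.03 to 10.3). Il7r was at 182 RPKM in CD4 against 145 in CD8 (1.26-fold, 1.23 to 1.29) and Il2rg, the common gamma chain, at 326 against 353 RPKM. Of 20 trafficking and adhesion genes 2 were at least 2-fold higher in CD4 and 5 in CD8, with a median of -0.05 at a percentile of 13.8, which was above 0 after rescaling to a sum of 1000000 (0.14) or to the housekeeping list (0.01). Ccr9, the gut homing receptor, was at 65.9 RPKM in CD8 against 4.27 in CD4 (15.4-fold, 14 to 17), and Itgb7 was at 521 RPKM in CD4 and 475 in CD8. Of 29 interferon stimulated genes 3 were at least 2-fold higher in CD4 and 1 in CD8, with a median of 0.11 at a percentile of 69.4. Ly6a, the Sca-1 gene, was at 158 RPKM in CD4 against 43.9 in CD8 (3.59-fold, 3.33 to 3.88) and Ly6c1 differed more, while Ifi47, the highest, was 1.16-fold higher in CD8. The 13 MHC class I and antigen processing genes had 0 members past the size rule and a median of 0.00 at a percentile of 52.1. H2-K1 was at 2007 RPKM in CD4 against 1866 in CD8, B2m at 2173 RPKM in CD8 against 1380 in CD4 (1.57-fold, 1.55 to 1.60) and Psmb8 at 1.39-fold higher in CD8.

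**Figure D3:**
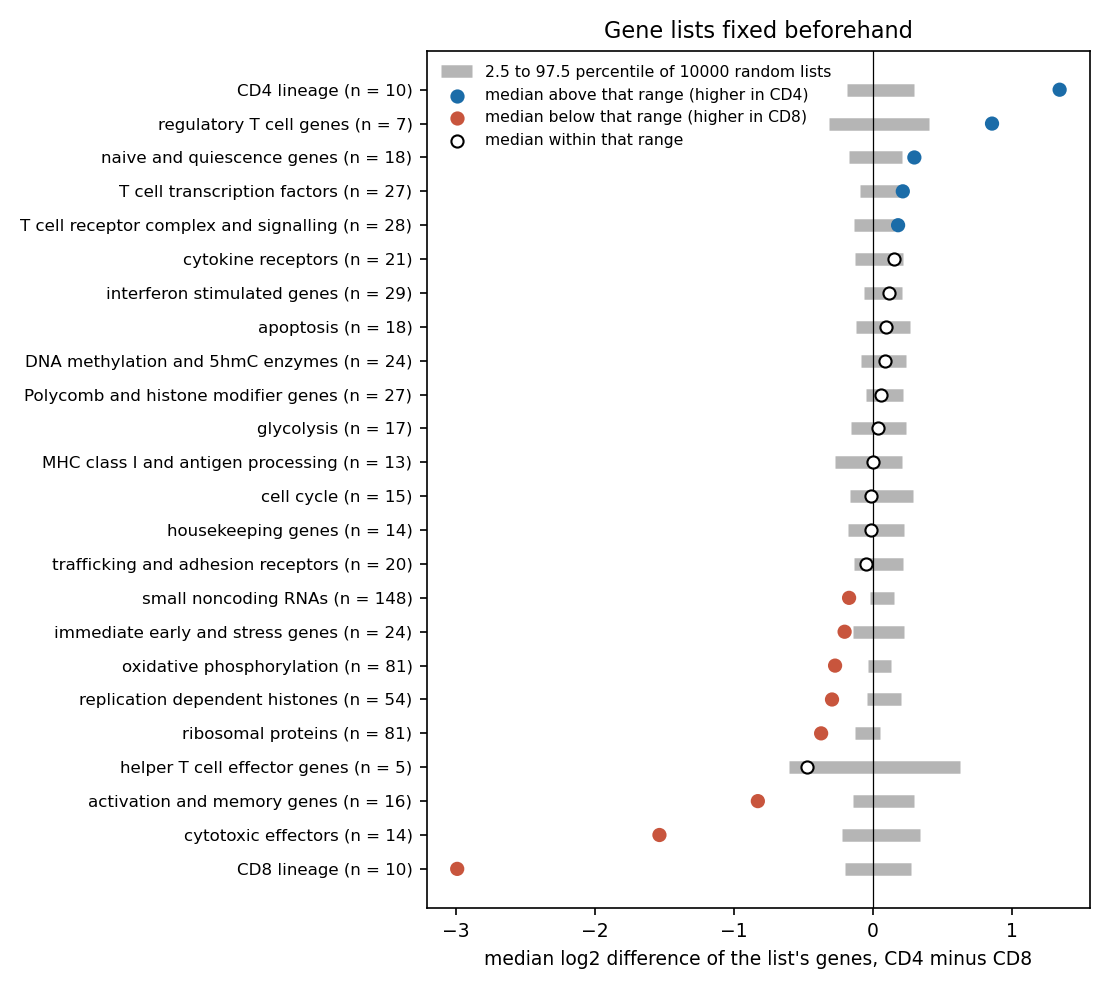
Median log2 difference (CD4 minus CD8) of the gene lists with at least 3 measured members, from 1 library per cell type, with n the number of measured genes. Grey bars span the 2.5 to 97.5 percentiles of 10000 random lists matched on mean expression, filled points lie outside that span, and the CD4 lineage (1.34) and CD8 lineage (-2.99) lists lie farthest apart.

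Ribosomal protein, oxidative phosphorylation and histone genes stood apart toward CD8. Of 81 ribosomal protein genes 77 were below 0 on the log2 scale and 8 were at least 2-fold higher in CD8, with a median of -0.37 at a percentile of 0. Rplp1 was at 4747 against 2269 RPKM (2.09-fold, 2.06 to 2.12), Rps26 at 2.74-fold (2.66 to 2.82), Rpl37 at 2.40-fold (2.33 to 2.47) and Rpl12 at 1.02-fold (1.01 to 1.03). Of 81 oxidative phosphorylation genes 66 were below 0 and 4 passed the size rule, with a median of -0.27 at a percentile of 0. Uqcrq, a complex III subunit, was at 24.6 against 4.88 RPKM (5.05-fold, 4.30 to 5.96) and Ndufc1 at 2.60-fold (1.97 to 3.46), and the highest, Atp5b (1.05-fold higher in CD4) and Cox4i1 (1.06-fold higher in CD8), were near equal. Of 54 replication dependent histone genes 7 were at least 2-fold higher in CD8 and 4 in CD4, with a median of -0.29 at a percentile of 0. Hist2h4 was at 54.8 against 16.3 RPKM (3.36-fold, 3.09 to 3.67), Hist1h1c and Hist1h4c at 2.20-fold and 2.17-fold higher in CD8, and Hist1h3g, with 43 and 4 reads, was higher in CD4 (10.4-fold, 3.77 to 39.8). Histone and ribosomal protein genes have near-identical copies, so single members are uncertain. The medians of the 3 lists were below 0 under every scaling, at -0.18, -0.10 and -0.13 in that order with each library rescaled to a sum of 1000000, where the median of the genes at 1 RPKM or more in both libraries was 0.27. In the same libraries shorter genes stood toward CD8. With all compared genes in 10 equal groups by length, these lists among them, the shortest group had a median of -0.22 and the longest 0.16.

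The 148 measured small noncoding RNA genes had a median of -0.17 at a percentile of 0, with 54 at least 2-fold higher in CD4 and 50 in CD8. Members went both ways, with 70 above 0 and 78 below it, so the percentile does not show a shared direction. The random lists were not matched on length. The shortest group of compared genes, of 48 to 1046 bases and with some of these RNAs among them, had a median of -0.22. A part played by length was not tested for this list. Rmrp, the RNA of RNase MRP, was at 1.86-fold (1.84 to 1.88) and Rnu73b at 2.14-fold (2.09 to 2.18) higher in CD8. Mir5109, with 1 read in CD4 and 194 in CD8, and Mir150, with 240 in CD4 and 12 in CD8, differed most. Rn45s, the ribosomal RNA precursor and outside the naming rule, took 0.357% of reads in CD4 and 3.08% in CD8. The 24 immediate early and stress genes had a median of -0.20 at a percentile of 0.50, with 3 at least 2-fold higher in CD8. Ier3, with 110 reads in CD8 and 4 in CD4 (28.5-fold, 10.8 to 107), and Nr4a2 (6.89-fold, 4.51 to 10.9) differed most, Junb was at 166 against 108 RPKM and Hsp90aa1 at 201 against 171 RPKM, both higher in CD8.

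The cell cycle, glycolysis, apoptosis and housekeeping lists lay within the range of random lists. The 15 cell cycle genes had a median of -0.01 at a percentile of 22.8 and 0 members past the size rule, with Pcna at 170 RPKM in CD4 and 141 in CD8, Mcm6 at 1.47-fold higher in CD8, and Ccnb1 with 61 and 22 reads. The 17 glycolysis genes had a median of 0.04 at a percentile of 43.5. Ldhb was at 18.4 RPKM in CD4 against 8.08 in CD8 (2.28-fold, 1.96 to 2.66), Hk2 had 185 reads in CD8 and 17 in CD4 (11.3-fold, 6.86 to 19.8), and the highest, Pkm and Ldha, were at 1.44-fold and 1.28-fold higher in CD4. The 18 apoptosis genes had a median of 0.09 at a percentile of 54.6. Pmaip1, the Noxa gene, had 175 reads in CD8 and 13 in CD4 (14-fold, 7.96 to 26.7), Bcl2a1b was 3.32-fold higher in CD4 (2.30 to 4.90) and has near-identical paralogs, and Mcl1 and Casp8 were both 1.28-fold higher in CD4. The 14 housekeeping genes had a median of -0.01 at a percentile of 31.0 and 0 members past the size rule, with Actb at 1.05-fold (1.04 to 1.05) higher in CD4, Rplp0 at 1.35-fold, Gusb at 1.63-fold and Tfrc at 1.60-fold higher in CD8. The cell cycle and housekeeping medians were above 0 with each library rescaled to a sum of 1000000 (0.17 and 0.18) or to the housekeeping list (0.04 and 0.04), and the glycolysis median was -0.05 after centring on the median gene.

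The lists of markers of other cell types each had 6 or fewer measured members. Of 5 measured B cell markers, Cd74 was at 7.76 RPKM in CD4 and 8.14 in CD8 and H2-Aa at 2.28 and 3.27 RPKM, while Cd79b was at 28.8 RPKM in CD8 against 2.14 in CD4 (13.5-fold, 10.4 to 17.7), and the list median was -0.24 at a percentile of 8.33. Of 6 myeloid markers Ctss was at 191 and 189 RPKM, Cd68 at 3.63 and 2.26 RPKM and Itgam at 1.62 and 0.559 RPKM, higher in CD4, and S100a8 had 5 and 23 reads, with a median of 0.01 at a percentile of 45.1. The 4 plasma cell markers had a median of 0.23 at a percentile of 73.2, with Xbp1 at 27.2 and 19.9 RPKM, Irf4 at 5.81 and 5.67 RPKM and Prdm1 with 158 and 21 reads. The 3 dendritic cell markers had a median of -0.95 at a percentile of 0.33, with Ccr9, also a trafficking gene, and Cst3, at 43.8 RPKM in CD8 against 22.2 in CD4, as its highest members. With no filter on low values this list lay within the random range (median -0.086). The globin genes Hba-a1, Hba-a2, Hbb-b1 and Hbb-b2, outside the naming rule, were listed at 0 in both libraries, as were Rpl26 and Ndufs5, so these zeros do not show low expression. The 1 measured erythroid marker, Car2, was at 3.35 RPKM in CD4 and 3.36 in CD8. The platelet list had Itgb3 and Itga2b (1.04 and 0.824 RPKM), and the stromal and endothelial list had Pecam1 at 105 RPKM in CD4 against 52.4 in CD8 (2.01-fold, 1.93 to 2.08).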

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

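Leaving Rn45s out of the totals and counting only genes with a counting interval on 1 side of 1 were chosen after seeing the data. Of 137 named genes, 110 stayed on their side of the size rule under every setting run in which they were kept. The filters leave a single gene's difference unchanged, so for genes only the pseudocounts and scalings could alter this. The filter at 5 RPKM kept 116 of the 137. Of 31 list medians, 28 stayed on their side of the random range. No named gene past the size rule and no list median outside the random range changed direction. The number of genes at least 2-fold higher in CD4 (247) was 428 with a pseudocount of 0.1 RPKM, 73 with 5 RPKM, 152 with a filter at 5 RPKM, which tests fewer genes, and 471 with each library rescaled to a sum of 1000000, and the number higher in CD8 (314) was 125 with a pseudocount of 5 RPKM and 208 with the filter at 5 RPKM. A pseudocount shrinks the differences of low genes by construction. Rescaling to a sum of 1000000 moved the median of the genes at 1 RPKM or more in both libraries by 0.19 and the share of genes higher in CD4 from 44.0% to 62.4%. With each symbol counted once, the RPKM summed to 457587 in CD4 and 530342 in CD8. The rescaling used the sums over all rows, repeated symbols included, which differ from these. With the lower sum in CD4, this rescaling raised CD4 values more by construction. It raised both libraries while the pseudocount stayed at 1 RPKM, which shrank the differences of low genes less. Why the sums differ was not tested. Leaving out small noncoding RNAs gave 193 and 264 genes, leaving Rn45s out of the totals 237 and 333, and requiring a one-sided counting interval 225 and 298. The regulatory T cell list (0.86) fell within the random range with no filter (0.20) and with a filter at 5 RPKM (0.039), and the dendritic cell markers (-0.95) with no filter (-0.086). The regulatory T cell markers (-0.48) left the range with a pseudocount of 5 RPKM (-0.30) and with a filter at 5 RPKM (-1.0). The members measured differ between filters, and other causes were not tested. With 1 library per cell type, depth limits counting error only, and differences between animals or sorts were not measured.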

Other observations

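The tests of the residual lineage transcripts were chosen after the values were seen. The tests of gene length and GC content were set before their results were seen, except that a condition was added afterwards, by which a match with a gap in mean expression above 1 on the log2 scale decides nothing where the matched genes lean the same way as the list.

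Further genes outside the naming rule, picked after their values were seen, differed between the libraries. The innate-like receptor gene Cd160 was at 11.5 RPKM in CD8 against 0.859 in CD4, the chemokine receptor gene Cxcr3 at 11.3 against 0.478 RPKM, and the cystatin gene Cst7 at 53.1 against 5.52 RPKM. The drug efflux transporter gene Abcb1a was at 8.14 against 1.53 RPKM and Tnfaip3, an inhibitor of NF-kB signalling, at 118 against 32.8 RPKM. Toward CD4 stood Tspan32 at 192 against 41.6 RPKM, the death receptor gene Tnfrsf25 at 74.6 against 20.8 RPKM, Ephb6 at 34.3 against 9.04 RPKM and Igfbp4 at 326 against 125 RPKM. Cd79b, at 28.8 RPKM in CD8, parted from the B cell markers Cd74 and H2-Aa, which were within 2-fold between the libraries.

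The coreceptor chain Cd8b1 kept 2.72% (2.53 to 2.93) of its CD8 level in the CD4 library, while Cd8a kept 0.482% (0.416 to 0.556). CD8 T cells left in the CD4 sort would bring both chains at 1 ratio. Among 5141 genes with 900 or more CD8 reads, 4 had intervals wholly below 0.5 of the Cd8b1 ratio, which were Cd8a, Plac8 at 0.512%, Nkg7 at 0.654% and Itgae at 0.882%. This argues against such cells as the whole source of the Cd8b1 reads. A candidate explanation that stays open and untested is transcription of Cd8b1 in naive CD4 cells.

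In the CD8 library the CD4 T cell markers kept 2.92% (2.69 to 3.15) of their CD4 level for Cd4, at 8.89 RPKM, 2.41% (1.98 to 2.92) for Zbtb7b and 2.95% (1.95 to 4.30) for Cd40lg. Among 5324 genes with 900 or more CD4 reads the lowest ratio was 2.24% (1.83 to 2.72) for St8sia6, and 0 of these genes had an interval wholly below 0.5 of the Cd4 ratio. Cd4 already had the largest log2 difference toward CD4 among them when it was taken as the reference, which left few genes room to lie below it, so the test decides nothing. A small share of CD4 T cells in the CD8 sort and low transcription of these genes in CD8 cells cannot be told apart.

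Ribosomal protein, oxidative phosphorylation and histone genes stood toward CD8. Across all compared genes, these lists included, the log2 difference rose with gene length (Spearman rho 0.199) more than with GC content (rho 0.0623). Against lists matched on mean expression and length, the oxidative phosphorylation median was at a percentile of 0.42 and the histone median at 0.50. The matched medians were -0.13 and -0.06 against -0.27 and -0.29, so length may account for part of these differences. The tests argue against length as the whole cause. This is weakened because the matched genes were longer on average, at 1180 against 1143 bases for oxidative phosphorylation and 1014 against 938 for histones. Matched on GC content both lists were at a percentile of 0. For the ribosomal protein genes the GC match also gave a percentile of 0, with a matched median of 0.05 that leaned the other way. Those matched genes were expressed less highly (mean log2(RPKM + 1) of 6.92 against 9.66). At that lower level genes of like GC content did not lean toward CD8, and at the list's own level GC content was not tested. The length match of the ribosomal protein genes gave 0.33, but the matched genes leaned the same way (-0.17). They were also expressed less highly (mean log2(RPKM + 1) of 7.38 against 9.66). Length therefore cannot be told apart from a difference between the cells for the ribosomal protein genes. Rn45s, outside the naming rule, took 0.357% of reads in CD4 and 3.08% in CD8 after ribosomal RNA depletion, and a link to this shift was not tested. A difference in ribosome content between naive CD4 and CD8 cells stays open and untested.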
